A study of Rattus norvegicus with 9 samples.

How the data were processed

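Messenger RNA was measured by sequencing in 9 libraries of rat synovial fibroblasts, the connective tissue cells of the joint lining. Per the labels' protocols, tissue pieces were digested with collagenase I and DNase I, polyadenylated RNA was captured on oligo(dT) beads, fragmented and reverse transcribed with random primers, and the adapter-ligated, amplified products were made into single-stranded circular DNA for sequencing. The 3 groups had 3 libraries each, taken from the titles: a control in routine culture, cells given the cytokine IL-1β, and cells given IL-1β and grown in a transwell with dermal fibroblasts in the upper chamber. A transwell holds the 2 cell types apart on either side of a porous membrane.

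The deposited values were FPKM, fragments scaled by transcript length and by the library's mapped fragments, for 17298 genes, per the file headers, written with 2 decimals. The aligner, the quantifier and the annotation are not given in the sources used here. Per the submitters' processing notes the genome build was GRCm38, which is a mouse build, whereas the rows carry rat gene identifiers: 16152 of the 17298 identifiers (93.4%) were found in the rat RefSeq gene table of assembly GRCr8, and 14487 symbols were equal to those in it. It was not settled which sequence the reads were aligned to. A mouse reference would lose rat reads to mismatches, by amounts that differ between genes, so levels of different genes are less comparable than the level of 1 gene across libraries. No coordinates are given for this reason. Symbols are those in the deposited table. Of the mitochondrially encoded genes listed beforehand, 0 were found among the genes kept, so the share of mitochondrial RNA was not examined.

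The values are therefore relative within a library: a few abundant genes that rise lower the values of all others. The FPKM sums were 679774 to 741810 per library. No counts were used, and the sequencing depth is unknown. The low values of 163 genes were examined for steps of whole reads, and only 1 to 8 per library could be used, which was too few to give relative depths. The precision therefore rests on the spread between 3 libraries. Of the genes kept, 40 had values identical to those of another gene in all 9 libraries, so such genes cannot be told apart. Where a gene was listed at 0, each library's value is given and no fold, because a 0 without counts can be a failed estimate.

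Genes with a mean FPKM of at least 1 over the 9 libraries were kept (11372 genes). Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 9 libraries and empirical Bayes moderation with a mean-variance trend and robust settings. The 3 contrasts were IL-1β minus control, co-culture minus IL-1β, and co-culture minus control. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes kept, with a threshold of 0.05, and the number of genes with an absolute log2 fold change of at least 1 is given beside each count. All log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and their errors are standard errors from the fit. Folds printed as such are ratios of mean FPKM.

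Before the data were examined, 36 gene lists were fixed, covering the inflammatory, matrix, metabolic and stress responses and markers of other cell types that the cultures could hold. Of these, 31 had at least 5 measured members and were tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 31 lists. Camera with an estimated correlation and fry were the alternatives. Counts of members past the threshold are over all genes tested, with the count adjusted over the list alone beside it where the numbers differ.

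The genes named were chosen by a rule fixed before the data were examined: for each contrast the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose groups did not overlap, from each list up to 3 members with the smallest p and 2 with the highest FPKM, the 8 genes with the strongest opposite changes in the first 2 contrasts, and 12 genes of interest. The text names a part of the genes within the rule, and 1 of them is not reported under the alternatives. Genes named outside the rule are marked where they occur.

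The first 2 contrasts share the IL-1β libraries with opposite sign, and the first and the third share the control libraries. Overlaps and correlations of these 2 pairs are therefore given beside the values from 100 simulated data sets without any effect. Their overlaps are also given beside the number that independent lists of the same lengths would share. The second and the third contrast share the co-culture libraries with the same sign, and genes past both are given beside the simulated data only. With 3 libraries the shared group cannot be split into parts of at least 2.

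The fit was tested on simulated data for 11372 genes. With changes of 0.25 on the log2 scale, 58% of changed genes were recovered for IL-1β minus control and 72% for co-culture minus IL-1β. With changes of 0.5 the share was 98% in each, and with changes of 1 or 2 it was 100% in each. Of the unchanged genes, 7 and 16 were called, respectively. These shares reflect the spread between libraries, whose median was 0.066 on the log2 scale (quartiles 0.051 and 0.089).

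Alternatives were a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, median-of-ratios scaling, quantile normalization, fits on the 6 libraries of the groups compared, library weights, the replicate number as a block, and leaving out each library in turn. Quantile normalization for the gene lists, and every alternative for the genes beyond both other groups, were added after the data were seen. Plots were drawn with matplotlib 3.10.9.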

Results

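RNA of rat synovial fibroblasts was compared between 3 conditions: routine culture (control), stimulation with IL-1β, an inflammatory cytokine, and stimulation with IL-1β together with dermal fibroblasts in the upper chamber of a transwell. Each condition had 3 libraries, and 11372 genes were tested. The design addresses how synovial fibroblasts respond to IL-1β and how the profile differs in co-culture with dermal fibroblasts. Levels are FPKM as mean ± SD over 3 libraries unless stated otherwise. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. The sequencing depth is unknown.

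The libraries separated by condition. Rank correlations across genes were 0.9946 to 0.9959 between libraries of the same group and 0.9584 to 0.9912 between groups. The first principal component held 75% of the variance. On it, control scored -24.3 ± 0.42, IL-1β 33.3 ± 0.12 and co-culture -9 ± 0.4, which placed co-culture 26.7% of the way from control to IL-1β. The gene with the highest level was Eef1a1, a translation elongation factor, in each control and co-culture library, and Mgp, which encodes matrix Gla protein, in each IL-1β library, at 11063 to 11684 FPKM. Both genes are named after their values were seen.

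**Figure D1:**
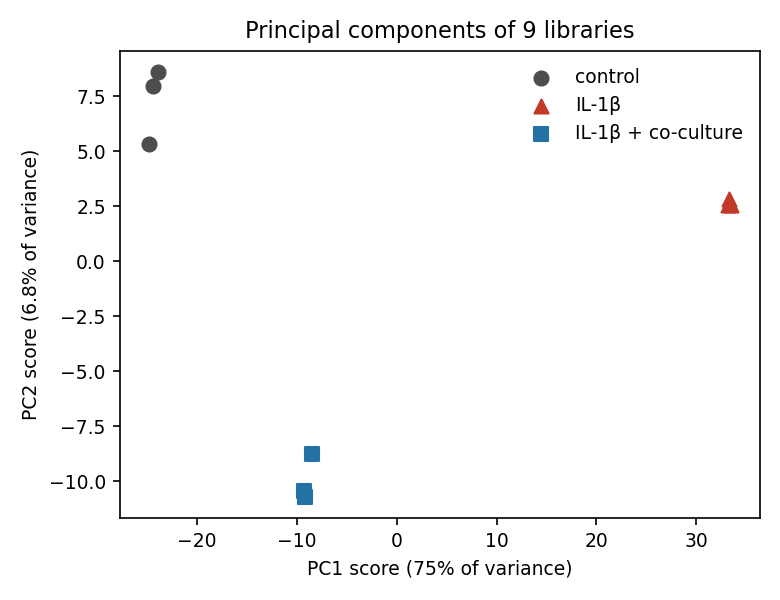
Scores of the 9 libraries on the first (horizontal axis, 75% of variance) and second (vertical axis, 6.8%) principal components of log2(FPKM + 1). Each point is a library. The co-culture libraries lie between the other groups on the first component, at a mean of -9, and apart from both on the second, at a mean of -10.

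IL-1β raised genes of inflammatory signalling and matrix breakdown and lowered genes of cartilage and collagen matrix. On the log2(FPKM + 1) scale, the largest rise was that of the gelatinase gene Mmp9 (gene ID 81687), from 0.59 ± 0.035 to 621 ± 8.1 FPKM, a log2 fold change of 8.61 ± 0.04 (limma adjusted p = 8e-17). Csf3, which encodes granulocyte colony-stimulating factor, rose from 0.19 ± 0.035 to 328 ± 12.3 FPKM, and the neutrophil chemokine gene Cxcl2 from 0.07 ± 0 to 214 ± 15.6 FPKM. By the ratio of mean FPKM these 2 rose more than Mmp9, 1730-fold and 3060-fold against 1050-fold, from levels near 0. Csf2 was listed at 0 in each control library and at 137, 127 and 136 FPKM with IL-1β. The largest fall on the log2(FPKM + 1) scale was that of Lrrc17, from 13.8 ± 0.96 to 0.63 ± 0.14 FPKM (log2 fold change -3.19 ± 0.1, adjusted p = 1.4e-10), followed by Tgfbi, a matrix adaptor protein gene, from 175 ± 2.07 to 20.2 ± 0.67 FPKM.

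With IL-1β, 5874 of the 11372 genes passed the threshold, 2330 higher and 3544 lower, and 524 of them changed by at least 1 on the log2 scale, 312 higher and 212 lower. The share of higher genes among the calls was 39.7%, but 51.4% after median-of-ratios scaling (2961 higher and 2799 lower) and 41.7% after quantile normalization (2463 higher and 3448 lower). The median log2 fold change of all genes was -0.044.

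The secreted mediators rose as groups. Of 20 measured cytokine and growth factor genes, 18 were higher and none lower, with a median log2 fold change of 2.71 (camera adjusted p = 2.4e-16). Il6, an acute phase inducing cytokine, rose 27-fold, from 39.5 ± 2.66 to 1069 ± 42.3 FPKM, and Il11 rose 114-fold to 130 ± 1.12 FPKM. Transcripts of IL-1 itself also rose, Il1a from 0.057 ± 0.023 to 85.3 ± 3.43 FPKM and Il1b from 0.11, 0 and 0.06 FPKM in the control libraries to 6.18 ± 0.52 FPKM. Of 17 chemokine genes, 14 were higher and 1 lower, or 15 and 1 adjusted over the list alone (camera adjusted p = 3e-13). Among them Ccl20 rose 55.1-fold, Cxcl1 17.3-fold to 5794 ± 222 FPKM and Ccl2, a monocyte attractant, 5.82-fold to 6820 ± 202 FPKM. Of 15 genes of prostaglandin and nitric oxide synthesis, 10 were higher and 4 lower (camera adjusted p = 0.00023). The cyclooxygenase gene Ptgs2 rose 55.6-fold to 500 ± 10.3 FPKM and the prostaglandin E synthase gene Ptges 22.9-fold to 932 ± 15.4 FPKM, whereas Ptgs1 fell from 170 ± 3.37 to 152 ± 3.58 FPKM. Nos2 was listed at 0 in each control library and at 23, 20.4 and 22.2 FPKM with IL-1β.

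Acute phase and complement genes, 16 of 18 higher and 2 lower (camera adjusted p = 4.4e-13), included Lcn2, an iron-sequestering protein gene, which rose 92.1-fold to 3963 ± 131 FPKM, and the complement gene C3, which rose 47.2-fold to 266 ± 10.8 FPKM. Of 30 genes of NF-kB signalling and its feedback, 25 were higher and 2 lower (camera adjusted p = 3.2e-13), among them the inhibitor gene Nfkbia, 4.39-fold. Each of these 5 lists also passed with an estimated correlation between genes. Macrophage and leukocyte markers did not pass, with 2 of 5 higher and 1 lower, or 3 and 1 adjusted over the list alone, and a median of 0.66 on the log2 scale (camera adjusted p = 0.12, but 0.04 without co-culture replicate 2 and 0.044 without co-culture replicate 3). Among them the monocyte receptor gene Cd14 went from 13.5 ± 0.58 to 22.7 ± 0.82 FPKM and Cd68 from 2.3 ± 0.45 to 4.77 ± 0.88 FPKM. The lysozyme gene Lyz2 fell, from 10.65 ± 0.9 to 7.99 ± 0.4 FPKM (limma adjusted p = 0.0013).

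Matrix-degrading enzymes rose in part. Of 20 measured metalloproteinase and aggrecanase genes, 11 were higher and 4 lower, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.00025). The stromelysin gene Mmp3 rose 18.2-fold to 3556 ± 35.3 FPKM and the collagenase gene Mmp13 10.7-fold to 780 ± 33 FPKM. The collagens went the other way, with 14 of 19 lower and 3 higher and a median log2 fold change of -0.73 (camera adjusted p = 0.00036, and adjusted p = 0.41 with an estimated correlation). Col1a1 went from 3170 ± 113 to 1587 ± 54.8 FPKM and Col3a1 from 1734 ± 35.7 to 425 ± 6.13 FPKM. Other matrix genes were split, 19 of 31 lower and 8 higher, or 20 and 8 adjusted over the list alone (camera adjusted p = 0.053), with Dcn, the gene of the proteoglycan decorin, up 4.86-fold. Contractile genes of myofibroblasts were lower in 14 of 21 and higher in 3 (camera adjusted p = 0.00045), as with smooth muscle actin, Acta2, from 158 ± 4.51 to 59 ± 1.32 FPKM. Pericyte and smooth muscle markers did not pass, with 4 of 7 lower and 2 higher and a median of -0.34 on the log2 scale (camera adjusted p = 0.36). The lubricin gene Prg4, of the synovial lining, rose 3.09-fold within a list of 13 lining and hyaluronan genes of which 7 were higher and 5 lower (camera adjusted p = 0.014, and adjusted p = 0.075 with an estimated correlation). Tgfb1 rose 1.28-fold, within a list of TGF-beta genes that did not pass (14 of 29 higher and 11 lower, or 14 and 12 adjusted over the list alone, camera adjusted p = 0.23).

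Chondrocyte and adipocyte markers were lower. Of 8 chondrocyte marker genes, 6 were lower and none higher (camera adjusted p = 0.00033), including Col2a1, from 157 ± 6.39 to 18.1 ± 1.4 FPKM, and the aggrecan gene Acan, from 24.1 ± 0.81 to 2.22 ± 0.032 FPKM. Adipocyte marker genes were lower in 8 of 10 and higher in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00074), with Adipoq, the adiponectin gene, at 38.6 ± 1.95 and 14.2 ± 0.12 FPKM. Cholesterol synthesis and uptake genes were lower in 22 of 22 (camera adjusted p = 2.3e-09), among them Hmgcs1, a synthase of that pathway, with a log2 fold change of -0.91 ± 0.03. Cell cycle genes were lower in 24 of 34 and higher in 2, by a median of -0.15 on the log2 scale (camera adjusted p = 0.0025, and adjusted p = 0.23 with an estimated correlation), and 18 were lower after median-of-ratios scaling. Of 19 interferon-stimulated genes 14 were lower and 2 higher, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.23 with an estimated correlation, and 0.061 without co-culture replicate 1), with Ifit2 at 12.8 ± 0.41 and 7.48 ± 0.44 FPKM. In all, 14 of the 31 lists passed, and 10 with an estimated correlation.

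**Figure D2:**
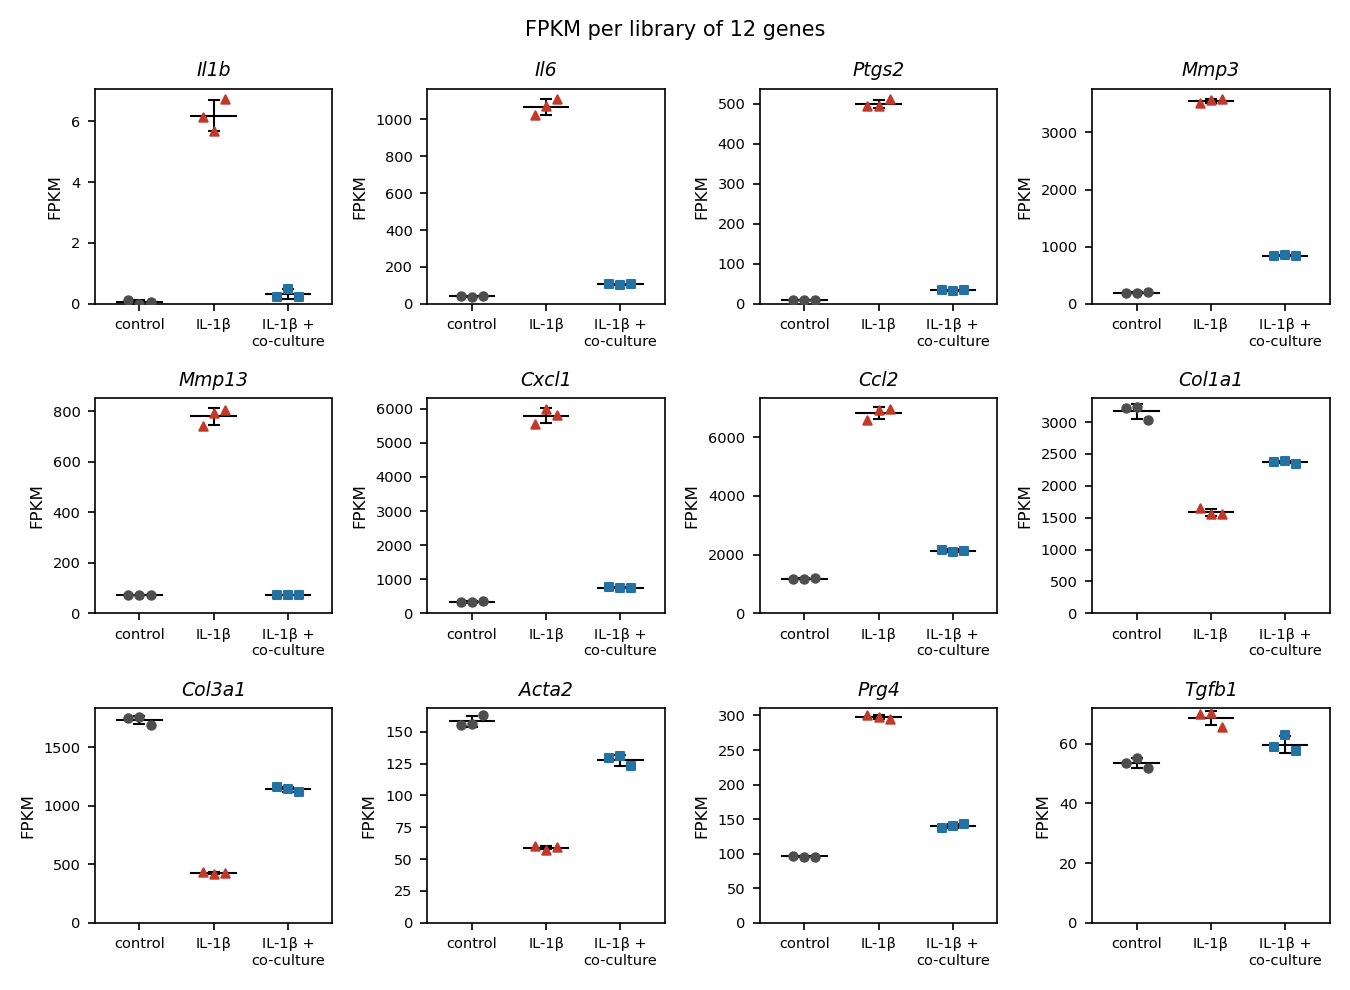
FPKM (vertical axes, linear, from 0) in each of the 9 libraries for the 12 genes fixed before the data were examined, by group. Points are libraries, long horizontal lines are means and error bars are the SD over 3 libraries. The first 7 genes are highest with IL-1β, and Mmp13 in co-culture (71.6 FPKM) lies at the control level (73.2 FPKM).

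Co-culture with dermal fibroblasts was next compared with IL-1β alone, to see which part of the IL-1β profile differed in co-culture. The labels do not say whether the other groups had an empty insert, nor how stimulation and co-culture were timed, and no group analysed here had co-culture without IL-1β. The comparison therefore covers the insert and the medium as well as the dermal fibroblasts. The genes that IL-1β had raised most were lower. Csf2 was listed at 0.78, 0.36 and 0 FPKM in the co-culture libraries, against 127 to 137 FPKM with IL-1β alone. Cxcl2 went from 214 ± 15.6 to 1.23 ± 0.096 FPKM, with a log2 fold change of -6.59 ± 0.06 (limma adjusted p = 1.8e-14), and Mmp9 from 621 ± 8.1 to 17 ± 1.07 FPKM. On the log2(FPKM + 1) scale, the largest rise was that of Car3, a carbonic anhydrase gene, from 7.37 ± 0.79 to 43.7 ± 0.52 FPKM (log2 fold change 2.42 ± 0.06, adjusted p = 3.5e-11). It was followed by Tgfbi, to 97.2 ± 1.44 FPKM, Lrrc17, to 6.52 ± 1.01 FPKM, and Acan, to 13.3 ± 0.77 FPKM. By the ratio of mean FPKM the order differed, with Lrrc17 up 10.4-fold, Acan 5.99-fold and Car3 5.93-fold.

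In this comparison 5687 genes passed the threshold, 3786 higher and 1901 lower, of which 298 changed by at least 1 on the log2 scale, 84 higher and 214 lower. Higher genes made up 66.6% of the calls, 50.4% after median-of-ratios scaling (2702 higher and 2655 lower) and 58.3% after quantile normalization (3199 higher and 2289 lower).

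The same 6 inflammatory and protease lists moved down. Cytokine and growth factor genes were lower in 17 of 20 and higher in none, or 18 adjusted over the list alone, with a median log2 fold change of -2.19 (camera adjusted p = 7.8e-18). Il6 was at 106 ± 2.7 FPKM, a log2 fold change of -3.32 ± 0.05 from IL-1β alone, and Il23a, a subunit gene of interleukin 23, was at 0.18 FPKM against 70 ± 3.8. Chemokine genes were lower in 13 of 17 and higher in 1 (camera adjusted p = 6.3e-12), with Cxcl1 at 753 ± 11.3 FPKM. The 1 chemokine gene that was higher was Cxcl13, a B cell attractant named here after its values were seen, with a log2 fold change of 0.46. Prostaglandin and nitric oxide genes were lower in 10 of 15 and higher in 4 (camera adjusted p = 7.1e-05), Ptgs2 standing at 33.7 ± 1.55 FPKM. Acute phase and complement genes were lower in 15 of 18 and higher in 3 (camera adjusted p = 2.9e-11), NF-kB genes lower in 23 of 30 and higher in 2, or 24 and 2 adjusted over the list alone (camera adjusted p = 7.6e-14), and metalloproteinase genes lower in 10 of 20 and higher in 2 (camera adjusted p = 4.9e-05). All 6 lists also passed with an estimated correlation.

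Contractile and cholesterol genes rose as groups, and matrix genes less uniformly. Collagens were higher in 13 of 19 and lower in 4 (camera adjusted p = 0.022, and adjusted p = 0.58 with an estimated correlation), and other matrix genes, higher in 18 of 31 and lower in 7, did not pass (camera adjusted p = 0.18). Col3a1 rose 2.68-fold to 1140 ± 22.1 FPKM and Col1a1 1.49-fold to 2370 ± 18.9 FPKM. Contractile genes were higher in 14 of 21 and lower in 1 (camera adjusted p = 0.00044), with Acta2 up 2.16-fold and the transgelin gene Tagln up 1.86-fold. Pericyte and smooth muscle markers did not pass, with 4 of 7 higher and 1 lower and a median of 0.36 on the log2 scale (camera adjusted p = 0.099). Chondrocyte markers were higher in 6 of 8 and lower in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0055, and adjusted p = 0.052 with an estimated correlation), and adipocyte markers higher in 7 of 10 and lower in 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.12 with an estimated correlation). Cholesterol genes were higher in 21 of 22 (camera adjusted p = 1.4e-06).

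Cell cycle genes were higher in 31 of 34 and lower in none, by a median of 0.31 on the log2 scale (camera adjusted p = 1.8e-08), a direction shared by median-of-ratios scaling (30 higher) and quantile normalization (31 higher). The replication helicase genes Mcm5 and Mcm3 had log2 fold changes of 0.45 ± 0.03 and 0.42 ± 0.03. Fibroblast markers were lower in 10 of 17 and higher in 3 (camera adjusted p = 0.00083). Lining and hyaluronan genes were lower in 6 of 13 and higher in 5, or 7 and 3 after median-of-ratios scaling and 6 and 2 after quantile normalization (camera adjusted p = 0.012, and adjusted p = 0.063 with an estimated correlation), with Prg4 at 140 ± 3.03 FPKM. The calls of 4 further lists were lost both with an estimated correlation and after median-of-ratios scaling. Macrophage and leukocyte markers were lower in 3 of 5 (camera adjusted p = 0.024, and adjusted p = 0.19 with an estimated correlation). Unfolded protein and integrated stress response genes were lower in 14 of 29 and higher in 8 (camera adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation), a call also lost without IL-1β replicate 2 (adjusted p = 0.053) or co-culture replicate 3 (adjusted p = 0.057). Ribosomal protein genes were higher in 24 of 45, but in 9 after median-of-ratios scaling and 33 after quantile normalization (camera adjusted p = 0.028, and adjusted p = 0.63 with an estimated correlation), a call also lost without IL-1β replicate 1 (adjusted p = 0.14) or co-culture replicate 1 (adjusted p = 0.16). IGF and FGF signalling genes were lower in 10 of 21 and higher in 6, or 12 and 6 adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.2 with an estimated correlation, and 0.059 without IL-1β replicate 1). In all, 18 lists passed, and 10 with an estimated correlation. Dermal fibroblast markers did not pass, with 5 of 12 higher and 5 lower, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.48).

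The changes with IL-1β and with co-culture were set side by side. Of the genes past the threshold in both comparisons, 4567 changed in opposite directions, 1669 that rose with IL-1β and were lower in co-culture and 2898 that fell and were higher. Only 36 changed in the same direction in both. Independent lists would share 1569 genes in opposite directions. Simulated data without an effect gave at most 1, but they hold no IL-1β response, so they do not gauge the shared libraries' part in genes that respond. The strongest opposite changes by p-value were those of Mmp9, Cxcl2 and Mmp13. Because both comparisons use the same IL-1β libraries with opposite sign, part of the excess may come from those libraries. Across genes, which are not independent replicates, the log2 fold changes had a covariance of -0.208, against -0.0053 in simulated data.

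Of the 524 genes changed by at least 1 on the log2 scale with IL-1β, 521 (99.4%) moved back past the threshold in co-culture, 312 of 312 that had risen and 209 of 212 that had fallen, and none moved further. Against control, 416 of the 524 (79.4%) were still past the threshold in the direction of IL-1β. The share of the log2 change left in co-culture had a median of 27.1% among genes that had risen (quartiles 16.9% and 36.5%) and 33.3% among genes that had fallen (quartiles 23.7% and 41.7%). It differed between genes: C3 kept 61.6%, Lcn2 54.5%, Mmp3 50.3% and Il6 29.7%, whereas Il11 kept 8.3% and Mmp13 lay at -0.9%. Among genes that had fallen, Cilp kept 75.6% and Acta2 21.9%. Where a level is near or under the pseudocount of 1, the log2 share depends on it in part, as for Cilp with IL-1β (0.3 FPKM) and Il11 in control (1.14 FPKM). On the linear FPKM scale the shares left were 22.3% for C3, 11.9% for Lcn2, 19.3% for Mmp3 and 6.5% for Il6. On that scale they were 87.3% for Cilp and 30.8% for Acta2.

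**Figure D3:**
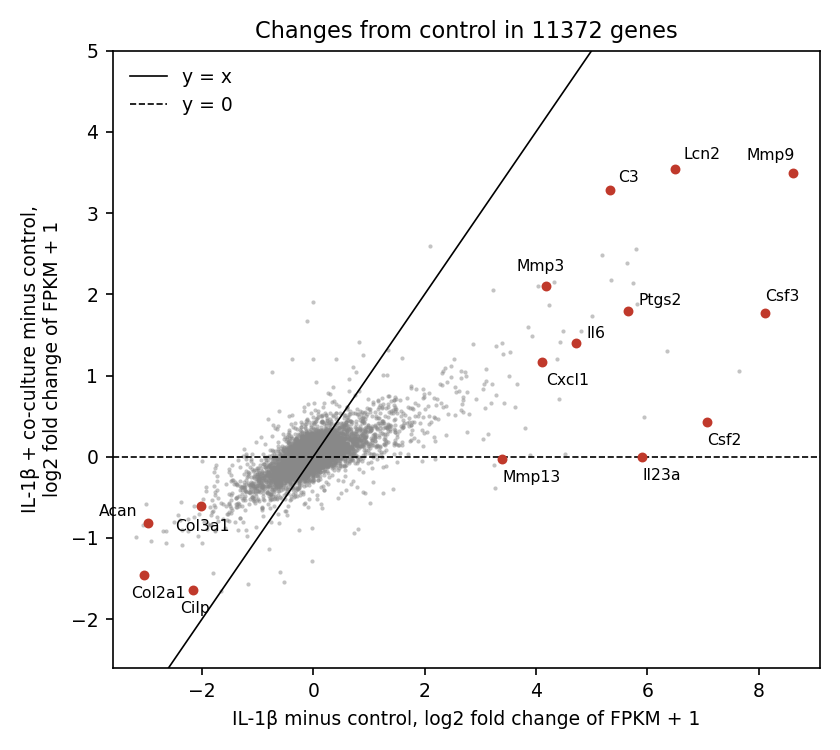
Log2 fold change of FPKM + 1 against control for 11372 genes, with IL-1β (horizontal axis) and with IL-1β and co-culture (vertical axis). Grey points are genes, red points are labelled genes, the solid line marks equal changes and the dashed line marks the control level. The labelled genes lie between the lines, except Mmp13 (-0.03 on the vertical axis) and Il23a (0), which lie at the dashed line. The axes have different scales and share the control libraries.

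Compared with control, co-cultured cells kept a smaller inflammatory profile. Lcn2 had the largest rise on the log2(FPKM + 1) scale, at 509 ± 19.5 against 43 ± 5.06 FPKM, with a log2 fold change of 3.54 ± 0.07 (limma adjusted p = 2.6e-10). It was followed by Mmp9, at 17 ± 1.07 against 0.59 ± 0.035 FPKM, and C3, at 63.7 ± 1.21 against 5.65 ± 0.44 FPKM. By the ratio of mean FPKM, Mmp9 was 28.8-fold above control and Lcn2 11.8-fold. Slpi, which encodes a leukocyte protease inhibitor, was 5.92-fold above control, and the Wnt antagonist gene Sfrp2 4.66-fold. The largest fall on the log2(FPKM + 1) scale was that of Cilp, which encodes a cartilage matrix protein, from 4.85 ± 0.28 to 0.88 ± 0.065 FPKM (log2 fold change -1.64 ± 0.07, adjusted p = 2.1e-08), followed by Col2a1, from 157 ± 6.39 to 56.4 ± 1.14 FPKM. Mmp13 was at 71.6 ± 0.49 FPKM, with a log2 fold change of -0.03 ± 0.03 (adjusted p = 0.56), and Il23a at 0.18 FPKM in both groups (adjusted p = 0.99).

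In this comparison 2307 genes passed the threshold, 1408 higher and 899 lower. Of these, 48 changed by at least 1 on the log2 scale, 42 higher and 6 lower, and the count was 85 with a pseudocount of 0.1. Higher genes made up 61% of the calls, 53.9% after median-of-ratios scaling (1190 higher and 1016 lower) and 46.4% after quantile normalization (1008 higher and 1166 lower). Among the 2307 genes, 70.3% were also called with IL-1β in the same direction, 830 higher and 792 lower in both, where independent lists would share 288 and 280, and 210 genes had opposite directions. These comparisons share the control libraries, and part of the excess may come from them. The covariance of the log2 fold changes was 0.0853, against 0.0054 in simulated data.

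Chemokine genes were higher than control in 13 of 17 and lower in 1, or 15 and 1 adjusted over the list alone (camera adjusted p = 1.1e-14), and acute phase and complement genes in 15 of 18 and lower in 1 (camera adjusted p = 1.5e-14). Ccl2 was at 2127 ± 46 FPKM, 1.82-fold above control, and Cxcl1 2.24-fold above. Cytokine and growth factor genes were higher in 13 of 20, or 14 adjusted over the list alone (camera adjusted p = 1.1e-08), with Il6 2.69-fold above control. Prostaglandin and nitric oxide genes were higher in 8 of 15 and lower in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00041), with Ptgs2 3.74-fold above. NF-kB genes were higher in 14 of 30 and lower in 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 3.9e-06, and adjusted p = 0.051 with an estimated correlation). The metalloproteinase list did not pass (8 of 20 higher, 4 lower, camera adjusted p = 0.1), its median (-0.04) and mean (0.39) differing in sign, while Mmp3 stood 4.31-fold above control. Il1b had an adjusted p of 0.049, with values over the alternatives from 0.008 to 0.66, and Tgfb1 one of 0.026, with values from 0.0071 to 0.11, so neither call held throughout.

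Chondrocyte, adipocyte and cholesterol genes lay below control as groups, while matrix genes were more divided. Collagens were lower in 13 of 19 and higher in 1, or 15 and 1 adjusted over the list alone (camera adjusted p = 3.2e-12, and adjusted p = 0.17 with an estimated correlation), Col3a1 with a log2 fold change of -0.6 ± 0.03 and Col1a1 of -0.42 ± 0.04. Other matrix genes were lower in 17 of 31 and higher in 9, or 18 and 9 adjusted over the list alone (camera adjusted p = 0.00081, and adjusted p = 0.096 with an estimated correlation), with Dcn 1.87-fold above control. Chondrocyte markers were lower in 7 of 8 (camera adjusted p = 9.4e-09), adipocyte markers in 9 of 10 (camera adjusted p = 2.4e-09) and cholesterol genes in 17 of 22 (camera adjusted p = 3.2e-12), with none higher in these 3 lists. Contractile genes did not pass (6 of 21 lower, 4 higher, camera adjusted p = 0.055), and Tagln had a log2 fold change of -0.04 ± 0.03 (adjusted p = 0.36).

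Cell cycle genes were above control in 21 of 34 and below in none, or 25 adjusted over the list alone, by a median of 0.15 on the log2 scale (camera adjusted p = 2.3e-08, and adjusted p = 0.053 with an estimated correlation), and 19 and 18 were above under median-of-ratios scaling and quantile normalization. Hypoxia and glycolysis genes were higher in 16 of 30 and lower in 1, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.13 with an estimated correlation), with the lactate transporter gene Slc16a3 1.4-fold above control. Lining and hyaluronan genes were higher in 6 of 13, with 0 lower or 1 adjusted over the list alone (camera adjusted p = 0.0042, and adjusted p = 0.053 with an estimated correlation), and Prg4 was 1.45-fold above. The unfolded protein and integrated stress response list was lower in 12 of 29 and higher in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00044, and adjusted p = 0.15 with an estimated correlation). Ribosomal protein genes were higher in 6 of 45, or 0 adjusted over the list alone and 3 after median-of-ratios scaling (camera adjusted p = 0.0017), a call absent with an estimated correlation (adjusted p = 0.55), without co-culture replicate 1 (adjusted p = 0.096) and after quantile normalization (adjusted p = 0.96, with 2 higher and 2 lower), the adjusted p over the alternatives ranging from 0.00013 to 0.96. In all, 15 lists passed, and 7 with an estimated correlation.

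Markers of dermal fibroblasts, macrophages and pericytes did not pass against control. Dermal fibroblast markers were higher in 3 of 12 and lower in 6 (camera adjusted p = 0.12), with Twist2 at 29.5 ± 0.89 FPKM in control, 86 ± 3.47 with IL-1β and 43.3 ± 3.95 in co-culture. The most abundant of them in control, Mfap5, was at 89.6 ± 1.13, 30.7 ± 3.38 and 55.7 ± 1.29 FPKM. Macrophage and leukocyte markers had 1 of 5 higher and 1 lower (camera adjusted p = 0.82), and pericyte markers 2 of 7 higher and 1 lower (camera adjusted p = 0.9). Of the endothelial, keratinocyte, skeletal muscle and Schwann cell lists, 2, 1, 2 and 2 genes reached the minimum level, too few to test. In none of the 3 comparisons did the lists for protease inhibitors, the TGF-beta pathway, dermal fibroblasts, pericytes, oxidative stress, immediate early genes, senescence, oxidative phosphorylation, the Wnt pathway or antigen presentation pass, with a lowest camera adjusted p of 0.05 for oxidative phosphorylation against control and 0.054 for protease inhibitors against IL-1β. The median, the mean and the test differed in sign for unfolded protein response, immediate early, oxidative phosphorylation and antigen presentation genes with IL-1β, and for TGF-beta, dermal, hypoxia, oxidative stress, immediate early and antigen presentation genes in co-culture against IL-1β. Against control they differed for metalloproteinases, protease inhibitors, oxidative stress, Wnt, and IGF and FGF genes.

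**Figure D4:**
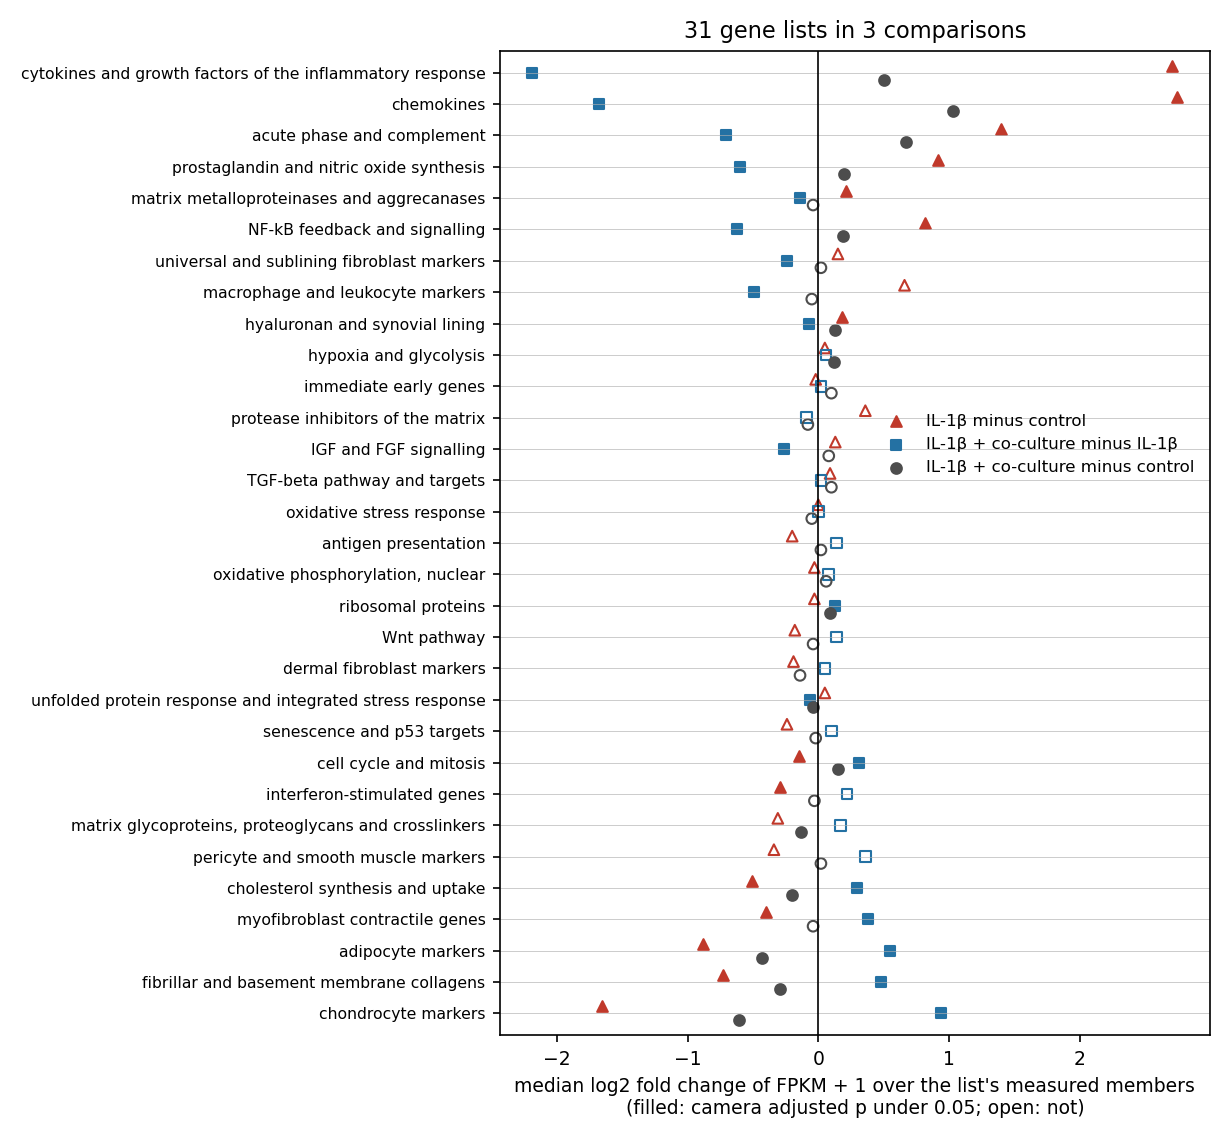
Median log2 fold change of FPKM + 1 (horizontal axis) over the measured members of 31 gene lists (vertical axis) in 3 comparisons. Red triangles show IL-1β minus control, blue squares co-culture minus IL-1β and grey circles co-culture minus control, filled where camera's adjusted p was under 0.05. For the cytokine list the medians were 2.71, -2.19 and 0.5, and for the chondrocyte list -1.66, 0.94 and -0.61.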

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

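Quantile normalization for gene lists and the counts of genes beyond both other groups were tried after the data were seen. The number of genes past the threshold stayed within 1.5 times its value under every alternative for all 3 comparisons and for opposite changes. Leaving out each library in turn gave 5242 to 5813 genes for IL-1β minus control, 5015 to 5656 for co-culture minus IL-1β, 1662 to 2306 for co-culture minus control and 4080 to 4256 in opposite directions. With a log2 fold change of at least 1 the ranges without 1 library were 519 to 526, 278 to 298 and 47 to 50. Over the other settings these counts moved further, over 361 to 688, 209 to 424 and 44 to 85. A pseudocount of 0.1 gave the 85 for co-culture minus control, since a smaller pseudocount enlarges the folds of low genes. The gene lists past camera's threshold ranged over 13 to 15, 16 to 19 and 15 to 17 without 1 library. An estimated correlation gave 10 lists for each of the comparisons with IL-1β alone and 7 for co-culture minus control, and fry gave 28, 30 and 26, as it does not compare a list with other genes. Of 561 gene values past the threshold among the genes chosen by the rule or named outside it, 49 were lost under at least 1 setting. Median-of-ratios scaling lost 24, leaving out co-culture replicate 1 lost 23 and leaving out control replicate 1 lost 22. Only 1 value changed sign, that of Rpl4 under quantile normalization for co-culture minus control (-0.02), for which the cause was not tested. The labels do not say that replicate numbers pair the libraries. Correlations of deviations from the group mean were -0.05 to 0.19 between libraries with the same number and -0.22 to 0.13 between others, and 6 of 9 libraries correlated best with one of their own number. With the number as a block, 5858, 5708 and 2227 genes passed, 4558 in opposite directions, 525, 299 and 47 with a log2 fold change of at least 1, and 14, 18 and 16 lists. Depth is unknown, so precision rests on the spread between 3 libraries.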

Other observations

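The tests of a mixture of RNA, of the FPKM scale, of dermal fibroblast RNA and of a lower IL-1β stimulus, and the counts of genes beyond both other groups, were chosen after the results were seen. Some genes in co-culture lay beyond both other groups instead of between them: 595 genes were past the limma threshold against both in the same direction, 514 higher and 81 lower. Simulated data without any effect, and so without an IL-1β response, gave at most 1. The lists compared were long, 3786 and 1408 genes higher and 1901 and 899 lower of 11372. Independent lists of these lengths would share many genes, so the 595 genes are not read as an excess. Both comparisons also use the same co-culture libraries with the same sign, and part of the count may come from those libraries. The count was 471 after median-of-ratios scaling, with 328 higher and 143 lower, 388 without control replicate 1 and 375 without co-culture replicate 1. Itga3, Angptl8, Lamb3, Cxcl13, Igfbp5 and Hprt1 are named here after their values were seen. The integrin gene Itga3 stood at 40.1 ± 0.57 FPKM in co-culture against 25 ± 1.5 in control and 25.2 ± 1.14 with IL-1β, and Angptl8 at 25.9 ± 1.13 against 17.1 ± 1.09 and 17.5 ± 0.4. The laminin gene Lamb3 and the chemokine gene Cxcl13 were also highest in co-culture, at 4.78 ± 0.14 and 27.9 ± 1.64 FPKM. Among the lower genes were those of the IGF binding proteins Igfbp5, at 0.67 ± 0.11 against 1.52 ± 0.39 and 1.74 ± 0.18 FPKM, and Igfbp3, at 21.2 ± 0.58 against 29.8 ± 0.9 and 31.3 ± 1.33, with Timp3, Mmp14 and the cystine transporter gene Slc7a11, which IL-1β had raised.

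Of the 12 genes of the unfolded protein and integrated stress response list that fell with IL-1β, 4 are given here, and differences between them were not tested. Trib3 was at 18.6 ± 0.74 FPKM in control, 8.68 ± 0.87 with IL-1β and 9.8 ± 0.71 in co-culture, so that 84.4% of its log2 change was left and the move back did not pass (limma adjusted p = 0.08), and the asparagine synthetase gene Asns kept 74.4%. The serine synthesis genes Phgdh and Psat1 kept 37.1% and 43.5%. The cell cycle inhibitor gene Cdkn2b was at 18.7 ± 0.3, 13.3 ± 0.68 and 11.9 ± 0.75 FPKM, and Slc16a3 kept 79.2% of its rise. Hprt1, a purine salvage gene, was listed at 1.21, 2.02 and 4.68 FPKM in control, 29.3, 30.6 and 33.9 with IL-1β, and 0, 0.01 and 15.8 in co-culture. These values differ widely within the control and co-culture groups, how the reads were assigned is not given in the sources used here, and they are not read as a change in expression.

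The co-culture libraries lay between control and IL-1β, with 4567 genes changed in opposite directions. Of 100 splits of the 9 libraries, 1 gave as many, the real one. The highest other was the real groups with their names exchanged (1622), and the highest that mixed the groups gave 40. Mixing groups this distinct widens the spread within them, so low counts follow from the separation itself. The splits show that the libraries separate by group. They cannot address chance differences between cultures, since the labels do not say whether libraries of a group came from separate cultures. A mixture of control and IL-1β RNA would leave 1 linear share in all genes, but the median share left was 14.8% in genes that rose and 45% in genes that fell, a difference of 30.2 percentage points where the median standard error of a single gene was 2 and 4.1 points, so it is not the whole cause. Nor is the authors' scale, since 82% of the opposite changes remained under the scaling that kept fewest. A share of up to 50% of dermal fibroblast RNA cannot take a gene below 50% of its IL-1β level. But 204 of the 312 genes that rose were below it in every co-culture library, so such a share is not the whole cause. If dilution alone had lowered these genes, the share needed per gene would have a median of 62.2% (quartiles 50.2% and 76.5%). A library holds only 1 such share, however, and it must cover the gene lowered most. By the ratio of mean FPKM, Mmp9 in co-culture was at 0.0274 of its IL-1β level and Cxcl2 at 0.00575. Dilution alone would therefore need libraries of almost only dermal RNA. Such libraries stay open, as does a smaller share beside another cause, since no group analysed here held dermal fibroblasts alone. The dermal markers had a median log2 fold change against control of -0.14, with a spread of 0.3. Of the 17 measured members, 12 were at 1 FPKM or more in control and 5 under it in both control and co-culture, with Mfap5 at 89.6 ± 1.13 FPKM in control. A lower effective IL-1β stimulus in the co-culture chamber cannot be told apart from an action of the dermal fibroblasts on the response, as 99.4% of the strongly changed genes moved back and no group had a lower dose.

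Of the 34 cell cycle genes, 19 were higher in co-culture than in both other groups, among them Mcm5, at 53.3 ± 0.93 FPKM against 42.6 ± 1.21 in control and 38.7 ± 0.81 with IL-1β. The authors' scale is not the whole cause, as 16 were counted under the scaling that gave fewest, nor did 1 co-culture library decide, as at least 15 were counted without each. A lower IL-1β stimulus alone, in a response that changes steadily with dose, would leave no gene below control with IL-1β and above it in co-culture, but 12 members were, and at least 7 under each scaling. These are transcript levels and not a measure of proliferation, which a count of dividing cells in each condition would give, and RNA of dermal fibroblasts, cell density, the age of the medium and a response that reverses at low doses were not tested for these genes.

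With 10 splits of 6 libraries no share under 0.05 can be reached, and in each comparison 1 split, the real one, gave as many. The real splits gave 5874, 5687 and 2307 genes, and the highest others 1, 0 and 1. For gene lists the real splits gave 14, 18 and 15, and the highest others 9, 12 and 12. The number of lists past the threshold therefore set the real splits apart far less than the number of genes did.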
